A study of Mus musculus with 8 samples.

How the data were processed

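RNA of 8 skin samples of irradiated mice, 4 labelled Irf1 knockout and 4 labelled wild type, had been amplified to Cy3-labelled cRNA and hybridised to 1-colour Agilent arrays, per the labels' protocols. The arrays were read with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes, and each scanner file holds 180870 spots. The processed signal is a spot's intensity on a linear scale after background subtraction and spatial detrending, with a surrogate value for spots not above background, and it carries no normalization between arrays, per the file headers. The mean and local background intensity of each spot are also in the deposited files, with flags for spots well above background, saturated or outlying. A second, deposited table of the authors holds log2 values. Its columns share 1 distribution, with a median of 3.17 in each, and track the log2 processed signals with slopes from 0.953 to 1.03; this was found from the values, and the software that made the table is not given in the sources used here. Its scale and direction follow the scanner values and it is not centred per probe.

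Groups were taken from the genotype labels, before the data were examined, as were the test between the groups and most alternatives. The comparison of custom with catalogue probes was not among the tests fixed then. Spots of 1 probe were averaged on the log2 scale, without control spots and outlier-flagged spots; saturated spots numbered 0. On each array under 50% of probes were well above background, so each array's 75th percentile was taken over the 52652 probes well above background on all 8 arrays and subtracted. A probe was tested if it was well above background on at least 4 arrays and had at least 2 values per group. Knockout and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all 64078 tested probes and a threshold of 0.05. Single values per array were compared with an exact two-sided permutation test. A probe not well above background on any array of a group has only a bound there, and its change is given as at least N-fold. Sequences were handled in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3; tables were read with data.table in R and figures drawn with Matplotlib 3.10.9.

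The limma step was tested on simulated data: 64061 probes with the real means and spreads, 4 against 4 arrays, and 200 changed probes. It called 0 of 50 probes changed 1.5-fold, 7 of 50 changed 2-fold, 38 of 50 changed 4-fold and 46 of 50 changed 8-fold, with 6 unchanged probes called. In this setting most 2-fold changes were missed. The real data gave 1002 calls, and more calls loosen the Benjamini-Hochberg cutoff, so these rates need not hold there. The search for over-represented words found a word planted among 64078 probes and gave no enrichment past 0.05 in held-out probes where none was planted (Fisher's exact p = 0.11). The ratio of called shares in held-out probes was 4.41 with the planted word and 1.88 with none. A single draw of each kind was made, with probes called independently. It does not show how often the search errs where probes share arrays.

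In the files the gene name and systematic name columns repeat the probe identifier for all non-control probes, and the gene table at hand holds neither probes nor sequences. So the planned readings of Irf1, the gene-level counts, the gene and cell-type lists, the coding and non-coding shares and the named-gene rules for those could not be run. The rule for named items asked for the 10 steepest rises and falls among called genes whose arrays separate fully; without names it was limited to 2 probes in each direction, by fitted log2 difference; where a group is not above background that difference has no exact rank. Custom and catalogue probes were told apart by the prefix of their identifiers. Overlapping probes were those sharing at least 30 consecutive bases. Over-represented words of 8 bases, each held by at least 10 tested custom probes, were ranked by binomial p among custom probes called higher, and the 10 leading words were then tested on catalogue probes that overlap no custom probe. A ridge regression on counts of 6-base words (penalty 300, 5 folds that keep overlapping probes together) predicted each array's values from the probe sequence.

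Alternatives covered quantile normalization, a percentile over all non-control probes, normexp background correction with an offset of 50, the authors' table, no filter and a stricter filter on dim probes, the replicate number as a block, array weights, a trended and robust variance prior, a 2-fold minimum and leaving out each array in turn. Values corrected for probe sequence, 1 probe per group of overlapping probes, a percentile within each probe class and a floor of 16 on the signal were added after the data were seen. The slide could not be entered as a block, because each group lies on 1 slide of its own.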

Results

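Total RNA from skin of the irradiated hind limb of male mice, 8 weeks old, was profiled on 8 one-colour microarrays. Of these, 4 arrays carried skin of Irf1 knockout mice and 4 carried skin of wild-type mice, and the irradiated area of every animal had received 35 Gy. Irf1 encodes interferon regulatory factor 1, a transcription factor induced by interferon. The series asks which RNAs differ between the genotypes after irradiation. No unirradiated skin was analysed here, and the labels do not give the time between exposure and sampling, so the comparison says nothing about the response to radiation itself. The samples are numbered within each genotype without a statement that each number is a different mouse. The p-values therefore measure the spread between these samples only, and the number of arrays limits the precision. Each array held 145548 non-control probes, of which 93857 had a custom identifier and 51691 an Agilent catalogue identifier. Between 58870 probes (wild-type replicate 1) and 68357 probes (knockout replicate 4) were well above background on an array. The share was 44.5% ± 2.39 in the knockout arrays and 42.5% ± 2.14 in the wild-type arrays (SD, n = 4 each), which did not differ past the threshold (exact two-sided permutation test, p = 0.20).

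The files do not pair probes with genes, so no probe was assigned to the knocked-out gene, and the genotype labels were not checked. Probe sequences were not compared with that of Irf1, so any probe, including those named below, may read it. For the same reason the gene groups fixed beforehand, from interferon response genes to markers of skin cell types, have no values here. The changed probes are therefore identified by their own sequence, with no genome position.

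Most probes that changed between the genotypes were higher in the knockout skin. Of 64078 probes tested, 1002 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 959 of them higher and 43 lower in the knockout than in the wild-type arrays. The median log2 difference was 0.016 over all tested probes. Among the probes called, which were selected for their size of change, it was 1.17 for those higher and -1.41 for those lower, or 1.13 and -1.26 with probes not well above background on any array of a group held at their bound. Changes of at least 2-fold made up 675 of the calls toward higher and 32 of those toward lower signal. The 4 knockout arrays lay wholly above or wholly below the 4 wild-type arrays for 7.79% of tested probes, where chance gives 2.86%. All knockout arrays lay on 1 slide and all wild-type arrays on the other, each scanned on its own, so genotype and slide cannot be told apart in this or any comparison below. The total rested on several arrays: without knockout replicate 1 it was 283, and with array quality weights it was 1590.

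Among the falling probes named by rule was A_52_P175685, whose sequence is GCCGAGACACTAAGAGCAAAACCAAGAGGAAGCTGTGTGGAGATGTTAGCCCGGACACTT. Its normalized log2 signal was -5.38 ± 0.35 in the knockout and -0.57 ± 0.41 in the wild type (SD, n = 4 each), and limma gave an adjusted p of 2.2e-04. It was well above background on all 4 wild-type arrays and on 0 knockout arrays, so its signal was at least 20.2-fold lower in the knockout. A_52_P1020860, with the sequence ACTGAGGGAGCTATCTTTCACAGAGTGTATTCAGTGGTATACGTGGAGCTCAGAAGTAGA, followed the same course. It stood at -6.28 ± 1.04 in the knockout, where it was not well above background on any array, and at -1.71 ± 0.74 in the wild type (SD, n = 4 each). That is at least 8.65-fold lower, with a limma adjusted p of 0.0049. On the log2 scale the difference of A_52_P175685 was -3.87 with signals floored at 16 and -2.15 with a normexp background correction; for A_52_P1020860 it was -2.73 and -1.44. Each bound sets the mean of the brighter group against the dim group's arrays held at no less than the weakest signal called well above background on that array, which ranged from 9.82 to 12.4; the floor of 16 lies above that and gives smaller folds.

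Of the rising probes named by rule, CUST_OEV3_078156 has the sequence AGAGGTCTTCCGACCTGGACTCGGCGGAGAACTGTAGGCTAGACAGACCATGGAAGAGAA. It was well above background on all 4 knockout arrays and on 0 wild-type arrays, at -3.60 ± 0.16 and -6.83 ± 0.25 (SD, n = 4 each). Its signal was thus at least 2.37-fold higher in the knockout, with a limma adjusted p of 2.2e-04, although the probe was dim, with a mean processed signal of 29.2 in the knockout. Its log2 difference was 0.68 with signals floored at 16, and 0.40 with a normexp background correction, where it no longer passed (limma adjusted p = 0.12). CUST_OEV3_021541, with the sequence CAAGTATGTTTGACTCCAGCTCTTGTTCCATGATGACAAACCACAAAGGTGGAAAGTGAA, was brighter. It averaged -1.17 ± 0.37 in the knockout and -4.28 ± 1.21 in the wild type (SD, n = 4 each), a difference of 3.12 ± 0.52 (SE) on the log2 scale with a limma adjusted p of 0.020; it was 2.69 with the floor and 1.36 with normexp. It was well above background on 3 of the 4 wild-type arrays, and its adjusted p rose above 0.05 when any of knockout replicates 1, 2 or 3 or wild-type replicates 2 or 4 was left out.

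**Figure D1:**
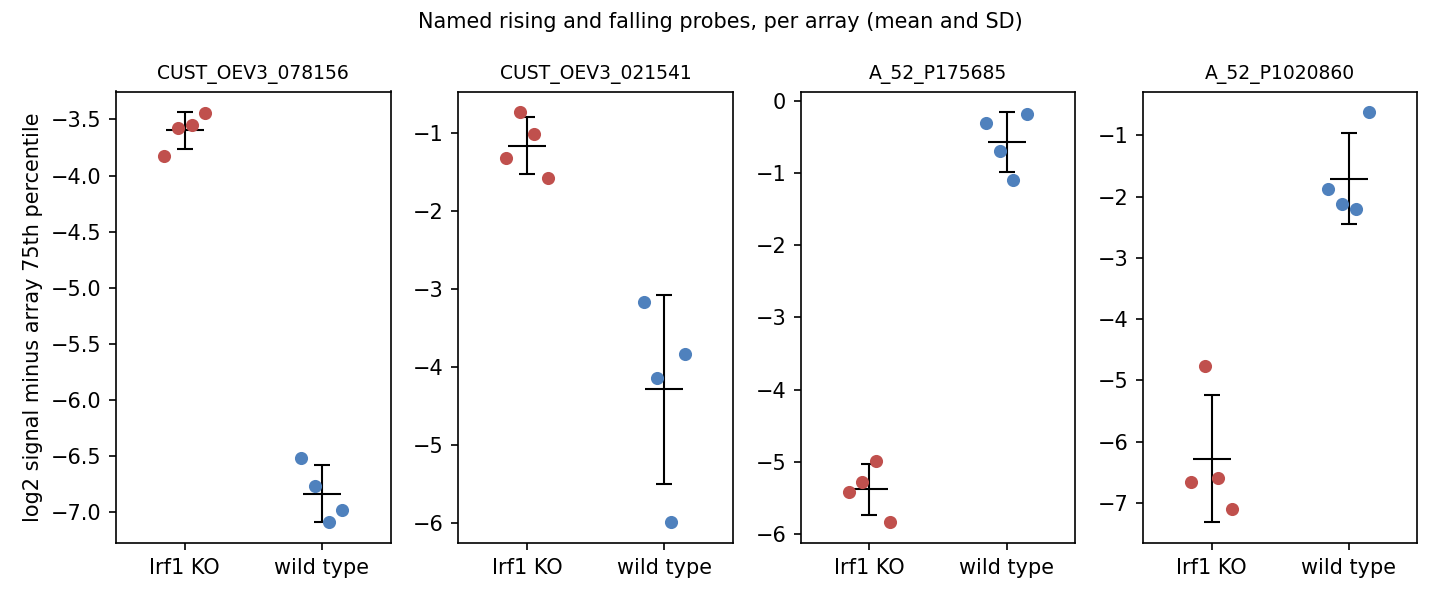
Normalized log2 signal (array 75th percentile at 0) of the 2 rising and 2 falling probes named by rule, with 1 point per array, knockout in red and wild type in blue; the bar is the mean and the whiskers the SD of 4 arrays. In each panel the knockout arrays lie wholly to one side of the wild-type arrays, with means of -5.38 and -0.57 for A_52_P175685.

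Custom probes were called higher more often than catalogue probes, but the shift between the classes did not pass a test over arrays. The comparison of the classes was not among the tests fixed beforehand. Among tested custom probes 2.34% were called higher in the knockout (712 of 30445), against 0.73% of catalogue probes (247 of 33633). The odds ratio was 3.24 (95% interval 2.79 to 3.76, Fisher's exact test, two-sided, p = 2.3e-64), a test that treats probes as independent although they share arrays and transcripts. In the other direction, 13 custom and 30 catalogue probes were called lower (odds ratio 0.48, two-sided Fisher's exact p = 0.031). The median log2 difference of all tested probes was 0.10 for custom and -0.04 for catalogue probes. On each array the median custom probe lay below the median catalogue probe, by -1.23 ± 0.04 log2 units in the knockout and -1.40 ± 0.17 in the wild type (SD, n = 4 each). With arrays as the unit, this difference of 0.17 did not pass (exact two-sided permutation test, p = 0.057, where 0.029 is the smallest p that 4 against 4 allows). Wild-type replicate 4 had the widest gap, at -1.64, and without it the difference was 0.095; it was 0.054 with normexp and 0.072 with no filter on dim probes. It passed with values corrected for probe sequence (0.14, exact permutation p = 0.029) and without wild-type replicate 3 (0.22, p = 0.029). That replicate, at -1.25, was the only wild-type array within the knockout range of -1.28 to -1.19. Leaving it out therefore separates the groups, and this pass is no independent support. What kind of RNA the custom probes target is not given in the sources used here.

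**Figure D2:**
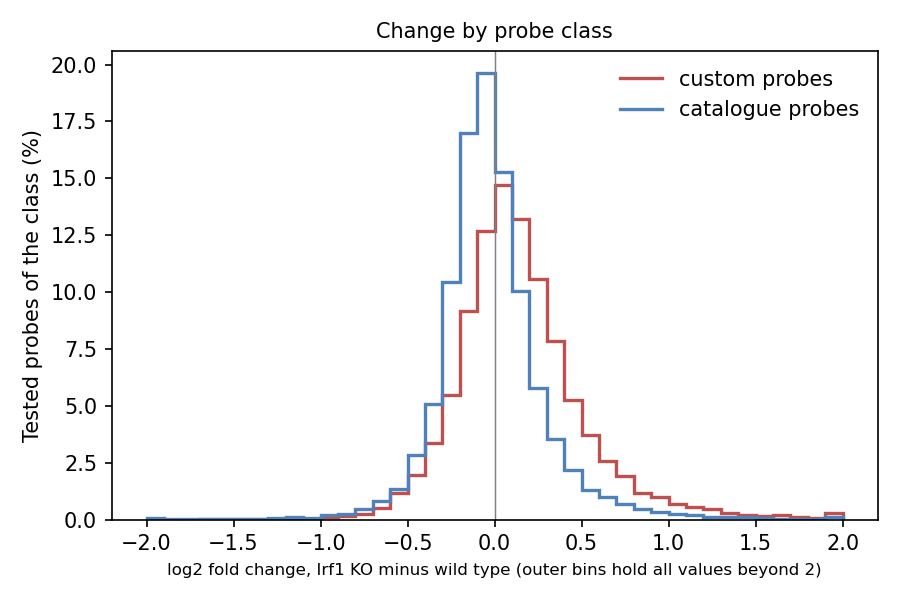
Share of tested probes (percent of the class, vertical axis) by log2 fold change of knockout against wild type (horizontal axis, bins of 0.1), for custom probes in red and catalogue probes in blue. The custom distribution is shifted to the right, with a median of 0.10 against -0.04.

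Among the control probes, the files name 2 for Gapdh and 2 for Pgk1, genes of the glycolytic enzymes glyceraldehyde-3-phosphate dehydrogenase and phosphoglycerate kinase; they are described because they are the probes with a gene in their name, a choice made after their values were seen. The probe Mouse-GAPDH_5 read 5.64 ± 0.25 in the knockout and 5.99 ± 0.74 in the wild type (SD, n = 4 each, exact two-sided permutation p = 0.40). Mouse-GAPDH_3 read 4.06 ± 0.40 and 4.35 ± 0.95 (exact permutation p = 0.57, n = 4 each). For Mouse-PGK1_3 the means were 2.65 ± 0.29 and 2.92 ± 0.58 (exact permutation p = 0.49, n = 4 each), and for Mouse-PGK1_5 they were 0.43 ± 0.23 and 0.73 ± 0.63 (exact permutation p = 0.51, n = 4 each). None of the 4 differences passed the threshold. Wild-type replicate 4 had the highest signal of all 8 arrays on each of these probes, for example 6.90 on Mouse-GAPDH_5 and 3.75 on Mouse-PGK1_3. Without it the Mouse-GAPDH_3 difference turned from -0.29 to 0.11, still not past the threshold.

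**Figure D3:**
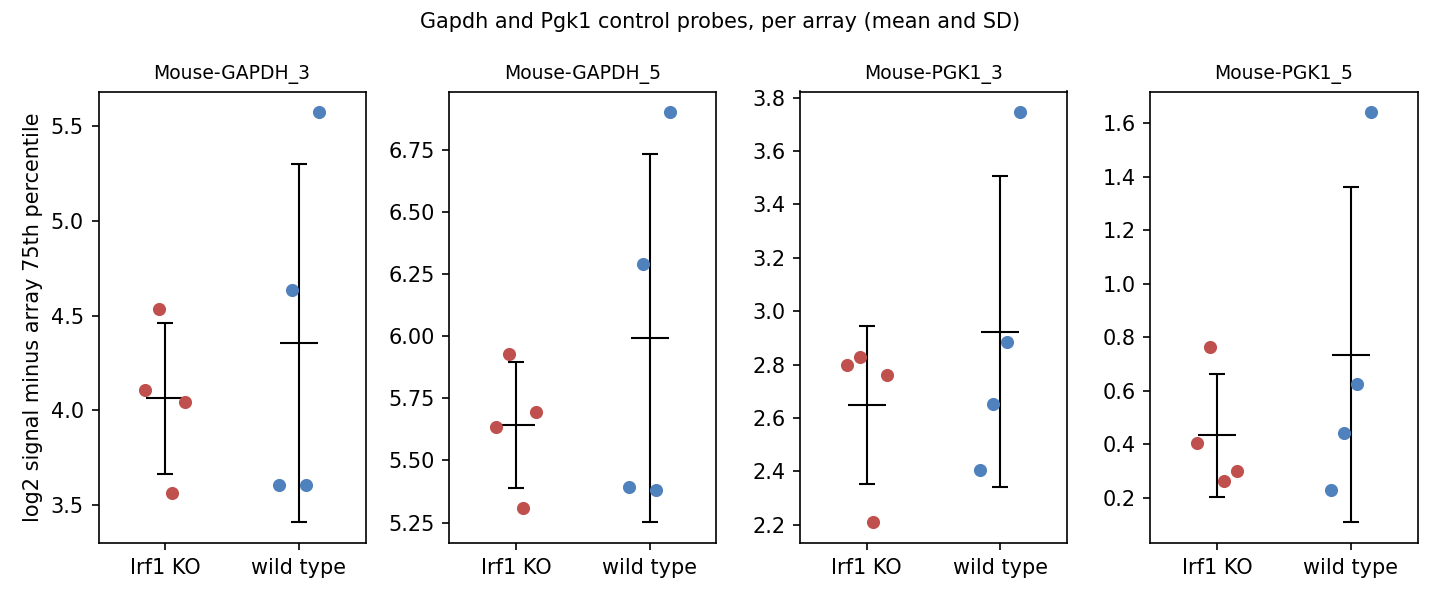
Normalized log2 signal (array 75th percentile at 0) of the Gapdh and Pgk1 control probes, 1 point per array, knockout in red and wild type in blue, with the mean and SD of 4 arrays. The groups overlap on each probe, and the highest wild-type point is replicate 4, at 6.90 on Mouse-GAPDH_5.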

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

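The tests of chance, scaling, slide, signal level, custom-probe pairs and wild-type replicate 4 were chosen only after the results were seen, as was the search for words; the 3 tests on the words were set before their outcome was known.

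The excess of probes called higher in the knockout, 959 against 43, was weighed against chance, scaling and slide. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many calls past the adjusted threshold. It gave 1002 and the highest of the others gave 10, which argues against chance for that count without excluding it. The smallest share that 35 splits allow is 2.86%. At an unadjusted p under 0.05 the real split had 6729 probes and 2 others had more. These were 10164 (knockout replicates 1, 2 and 4 with wild-type replicate 3) and 9536 (knockout replicates 1 and 4 with wild-type replicates 3 and 4). They point to a structure of the arrays that crosses genotype. The share of calls toward higher signal was at least 93.0% under each of 5 other scalings or sources of the values. So the excess did not rest on the choice among these, although the number called higher ranged from 648 to 838. The authors' table gave the same counts as quantile normalization (787 higher, 54 lower) and is no separate test. All 5 kept the median log2 difference between -0.061 and -0.0068, so a larger difference in scaling between the slides was not tested. A difference in slide, scan or labelling stays open and cannot be told apart from genotype, because 0 slides held both groups. The biological explanation, the genotype, is open on the same footing.

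Some probes called higher in the knockout shared short words, led by GTTCCCTC, which 64 tested custom probes held and 20 of those were called. Most probes called higher held none of the 10 words. Among custom probes 85 called ones held a word and 627 did not, and among held-out catalogue probes 15 did and 232 did not. Among 33472 held-out catalogue probes, 4.10% of the 366 with any of the 10 words were called higher, against 0.70% of the rest (Fisher's exact test, two-sided, p = 1.1e-07), whereas the reverse complements gave 0.73%. Base composition as the whole cause is argued against by a common odds ratio of 3.80 (95% interval 2.22 to 6.50) within strata of C and T content. It may account for part, since the ratio of called shares without strata was 5.85. With 1 probe per group of overlapping probes that ratio was 5.88. This step left 363 of the 366 word-holding probes and all 15 called ones. Probes at separate positions of 1 transcript are not grouped by it, so transcripts measured several times stay open. A labelled species that binds these words and differs between the slides may contribute: the median log2 difference was -0.04 with 0 words, 0.07 with 1 and 0.14 with 2 or more. Several words are copies of each other shifted by 1 base, such as GGTTCCCT and GTTCCCTC. So 2 or more words can be 1 longer stretch, and the order is no clear dose of binding sites. The shift of word-holding probes did not separate the groups (0.07 ± 0.08 against -0.09 ± 0.07, SD, n = 4 each, exact permutation p = 0.057). Even a full separation could not tell this explanation from a difference between genotypes, because each group lies on a slide of its own.

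Custom probes read higher against catalogue probes in the knockout, though not past the test over arrays, with medians of all tested probes apart by 0.15 on the log2 scale. Signal level is argued against, since within 10 bins of equal mean level the median gap was still 0.12. An effect of make shared by all custom probes is argued against by 176 pairs of a custom and a catalogue probe sharing bases. In these pairs the custom probe differed by -0.0087 (95% bootstrap interval -0.02 to 0.0069), where the classes differed by 0.15. The custom probes of the pairs lack the shift, with a median of -0.10 against 0.10 for all custom probes. An effect of make limited to other custom probes therefore stays open. Wild-type replicate 4 alone stays open: without it the difference between groups in the class gap was 0.095 ± 0.051 (SE), and 50% of the full difference is 0.086, too close to decide. The genotype and the slide remain untested as explanations.

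Knockout replicate 3 stood apart from its group on Mouse-PGK1_3, at 2.21 where the other knockout arrays lay between 2.76 and 2.83. It was the single such case in 24 groups of 4 values examined, and chance gives about 1 in 20. Of 12 control probes with an ERCC name, 1 was well above background on all 8 arrays and read 0.74 higher on the log2 scale in the knockout, with the groups fully apart (exact permutation p = 0.029, the smallest that 4 against 4 allows; 0.23 with p = 0.057 under normexp). The labels do not say whether ERCC RNA was added, so this signal is not known to come from a control RNA. Of the control probes with an ETG name, 1 was likewise above background on all arrays, with a knockout minus wild-type difference of 0.18 (exact permutation p = 0.34). The 6 E1A control probes above background on all arrays differed by -0.22 to -0.09, and another, above background on 7 arrays, read 0.48 higher in the knockout with the groups fully apart (exact permutation p = 0.029).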

How the results depend on the processing

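Values corrected for probe sequence, 1 probe per overlapping group, the percentile within probe classes and the signal floor were chosen only after the data were seen. The count of 1002 called probes fell to 448 (416 higher) with no filter on dim probes, where 145543 probes were tested, and rose to 1590 (1502 higher, 88 lower) with array weights. Leaving out 1 array gave 283 to 739 calls, 270 to 708 higher and 13 to 49 lower. The total moved by over 1.5 times without knockout replicate 1 (283), replicate 2 (418) or replicate 3 (665), and without wild-type replicate 1 (638), replicate 2 (479) or replicate 4 (509); these fits also hold fewer arrays. With the replicate number as a block 125 probes were called, 118 higher and 7 lower. In both groups the number is also the array's position on its slide. Deviations of same-numbered arrays correlated at -0.06, 0.0039, -0.33 and 0.18, which shows no steady pairing but cannot exclude one. Of the knockout arrays 0 of 4, and of the wild-type arrays 1 of 4, correlated best with their own number. Under the other alternatives the total lay between 687 (sequence-corrected, with 592 of the 959 and 34 of the 43 calls kept) and 1170 (trended and robust prior). Quantile normalization kept 769 of the 959 and all 43. The class difference of 0.17 passed the exact permutation test with sequence-corrected values (0.14) and without wild-type replicate 3, the only wild-type array within the knockout range. It ranged from 0.095 to 0.22 over the left-out arrays, and the cause was not tested. It was smallest with normexp (0.054, exact permutation p = 0.37) and with no filter on dim probes (0.072, p = 0.40). Over the left-out arrays the Mouse-GAPDH_3 difference ranged from -0.54 to 0.11 and that of Mouse-PGK1_5 from -0.47 to 0.0010, both turning sign only without wild-type replicate 4. Both falling named probes passed in the 21 alternatives that tested them, CUST_OEV3_078156 in 20 and CUST_OEV3_021541 in 15; the filter for probes well above background on all 8 arrays left out all 4 named probes. Dim probes limit the data: 90 probes called higher were not well above background on any wild-type array, and 10 of the 43 called lower were not on any knockout array. The planned slide block could not be fitted, and alternatives for Irf1, genes, gene lists and coding classes were not run because the probes have no gene names here.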

Other observations

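The tests here were chosen only after the data were seen, and no explanation was tested for any of these values. Probes detected in one genotype only were unequally divided: 218 probes were well above background on all 4 knockout arrays and on 0 wild-type arrays, and 15 showed the converse.

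Overlapping probes read alike. Across 1930 pairs of tested probes sharing at least 30 bases on the same strand, the log2 differences correlated with r = 0.77 (across probe pairs, which are not independent replicates). In 77 of these pairs at least 1 probe was called, and 97.4% of those had both probes on the same side of 0, with both called in 18. Across 295 pairs that share bases on opposite strands, r was -0.47, so a larger log2 difference on one strand tended to go with a smaller one on the other. The sides of 0 were not counted for these pairs.

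Probe sequence predicted part of the difference between the genotypes. Predictions from 6-base words, made for probes outside the training set, correlated with the log2 difference at r = 0.27 (0.27 among custom and 0.22 among catalogue probes). The share of probes called higher went from 0.31% in the lowest 10th part of the predictions to 3.84% in the highest. This was no property of the genotypes alone: 18 of the 35 splits of the 8 arrays into 4 and 4 gave a correlation at least as high, and the highest of the others was 0.50.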
